A study of Homo sapiens and Mus musculus with 34 samples.

How the data were processed

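Human coronary artery smooth muscle cells, primary cells grown from a coronary artery and used at passages 5 to 8, were measured by bulk RNA sequencing. In the knockdown experiment they had received control siRNA, AHR siRNA or TCF21 siRNA, with RNA collected 48 hours later per the labels' protocols, in 4 libraries each. In the overexpression experiment 4 libraries overexpressed AHR and 4 were its controls. Single-cell RNA sequencing was done on tdTomato-positive cells sorted from the ascending aorta and its root in lineage-traced mice, in 2 wild-type and 3 Ahr knockout libraries. Groups came from the labels alone. The labels do not say whether bulk replicates came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical. Whether the mouse libraries came from separate animals was not examined, so the same limit holds for their p-values. A further single-cell sample carries the library name of knockout replicate 1 on another lane but a wild-type genotype label. It was given no group and has no cells of its own in the matrix. The cells under that library name, which the authors' metadata calls knockout, were taken as knockout replicate 1. Reads of both lanes may be merged in them, so no cells were left out on account of that label. The ChIP-seq and ATAC-seq samples were not analysed here.

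The authors' knockdown tables hold raw read counts per RefSeq accession. Of counts from 1 to 49, 68.8% were even, as happens when both mates of a read pair are counted. The counting options are not given in the sources used here. The submitters' processing notes name FastQC, STAR, featureCounts, DESeq2 and the hg19 build for the human RNA libraries. The control counts were the same in both tables, so the 12 libraries were joined. Of 22847 accessions, 22265 matched a gene symbol in a RefSeq table of another assembly, used for names alone. Reads on accessions without a symbol were 0.709% of the total. Accessions sharing a symbol were tested separately, the deepest carrying the plain symbol. How reads shared by paralogs such as MMP3 and MMP10, or by overlapping genes, were counted is not given in the sources used here.

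The deposited overexpression table holds read counts divided by a size factor per library by the authors, a scaled signal per gene symbol for 27777 genes, with the authors' DESeq2 log2 fold changes and p-values beside it. All values were whole multiples of their column's step (100% within 0.01 reads), so whole reads were recovered. The single-cell matrix deposited by the authors holds a depth-corrected score: corrected UMI values, whose totals equalled the corrected totals of the authors' metadata in 4861 of 4861 cells and the raw UMI totals in 8. It covers 14869 genes, and the submitters' processing notes name Cell Ranger, Seurat and mm10. The authors' kept cells had 465 to 3994 genes and at most 9.99 percent mitochondrial UMIs. Doublet removal is not given in the sources used here, and no caller was run because raw counts per gene were not used here. Cell classes and clusters are the authors' annotation. SMC, FMC, CMC and MP are its class names, for smooth muscle cells, fibromyocytes, chondromyocytes and macrophages.

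Sequencing depth was 31602203 to 44088554 reads per knockdown library and 40273386 to 58271500 per overexpression library. Wild-type replicates 1 and 2 held 1677 and 1650 cells with medians of 6164 and 6160.5 raw UMIs. Knockout replicates 1, 2 and 3 held 686, 513 and 335 cells with medians of 10269.5, 12928 and 12500 raw UMIs. Genotype, depth and library naming therefore change together. The wild-type libraries share 1 lane number and the knockout libraries used others.

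Knockdown counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM, default expression filter) in a single fit of 12 libraries with the set code of the labels as a term. The control libraries thus serve both knockdowns, and AHR knockdown was also compared directly with TCF21 knockdown. Because the overexpression table is not raw counts, limma 3.58.1 was used on log2(value + 1) with a mean-variance trend. Because the single-cell matrix is not raw counts, the planned count model was replaced by limma on log2(mean per library + 0.01), for genes with a mean of at least 0.02 corrected UMIs per cell. It was run over all cells and in classes with at least 20 cells in every library. The fewest were 53 SMC and 40 FMC cells in knockout replicate 1 and 32 CMC cells in knockout replicate 3. On the log2(value + pseudocount) scale the change of low genes is understated. Two-sided p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Fits were tested on simulated data with 200 changed genes. At 1.5-fold, 77% were recovered for AHR knockdown, 75% for TCF21 knockdown, 73.5% for the direct contrast and 65.5% for overexpression, and 8.3%, 5.1%, 7.5% and 5.8% of the calls were false, above the 5% aimed at. At 4-fold, 61.5% were recovered over all mouse cells, 73.5% in the SMC class, 34.5% in the FMC class and 31% in the CMC class, with 2.4%, 2.6%, 2.8% and 3.1% of calls false. The simulated mouse libraries had the same spread per gene in both genotypes and no difference in depth or overall shift. The real libraries differ in these, so the mouse rates need not hold for them.

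Before the data were examined, 21 gene lists were fixed: AHR battery, AHR complex, SMC contractile, modulated SMC, chondrogenic, matrix, matrix proteases, TGF-beta response, inflammatory cytokine, interferon response, cell cycle, NRF2 response, unfolded protein and amino acid stress, hypoxia, sterol synthesis, immediate early, coronary disease locus, endothelial, leukocyte, fibroblast and pericyte. The mouse lists take orthologs of the same name. Lists of at least 3 measured members were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01 and again with an estimated correlation. Its p-values were adjusted over the lists of a comparison. In passages on the lists, the adjusted p that closes a list's entry comes from camera. It belongs to the list, not to the gene named before it. A member counts as risen or fallen when it passed the threshold over all genes; counts adjusted over the list alone stand beside. The rule for named genes was also fixed then: AHR and TCF21; the 6 largest rises and falls among called genes with a mean log2 CPM of at least 2 (mouse 4) and no overlap between groups; up to 3 called members per list by adjusted p, or the most abundant member where none was called; all measured members of the AHR battery and, in mouse, the chondrogenic list; and the 5 shared genes per direction with the largest smaller change for overlaps. Y-linked genes, XIST and TSIX were left out of the human tests. Some genes that the rule names are not reported here.

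Overlaps between comparisons were set against independent lists, with Fisher's exact test, and for the shared controls against 20 simulations of unchanged groups and against controls divided between the knockdowns. Shares of cells were compared by exact two-sided permutation of library shares, with 95% Clopper-Pearson intervals. The upper limit for a count of 0 is 3 cells of the total. Intervals and such limits cover counting error only. Python 3.11.15, R 4.3.3 and DESeq2 1.42.0 were used besides.

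Alternatives planned before the data were examined were DESeq2, other size factors, no or stricter filters, no set term, the replicate number as a block, fits on the 2 groups alone, overexpression without the AHR counts, other cell filters and denominators, an estimated list correlation, and leaving out each library. Added after seeing the data were halved knockdown counts, edgeR and TMM factors on the recovered reads, mouse means scaled to the same total, a pseudocount of 0.1 for mouse means, and cells of 6000 to 12000 raw UMIs.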

Results

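RNA was measured in primary human coronary artery smooth muscle cells after knockdown or overexpression of AHR, the ligand-activated aryl hydrocarbon receptor, and after knockdown of TCF21, a transcription factor encoded at a coronary disease locus. The knockdown experiment had 4 libraries each of control siRNA, AHR siRNA and TCF21 siRNA, with 31602203 to 44088554 reads per library. The overexpression experiment had 4 AHR and 4 control libraries with 40273386 to 58271500 reads. Single cells of the ascending aorta and its root came from 2 wild-type and 3 Ahr knockout mouse libraries, sorted for viability and for tdTomato. Those libraries held 4861 cells, with 6164 and 6160.5 median raw UMIs per cell in the wild-type libraries and 10269.5, 12928 and 12500 in the knockout libraries. The comparisons ask which genes follow AHR in these cells, how far its targets overlap with those of TCF21, and whether loss of Ahr changes the fates of smooth muscle cells in the vessel wall.

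The targeted transcripts moved in the labelled direction in every human library. AHR stood at 78.2, 77.0, 73.1 and 79.0 CPM in the control libraries and at 10.0, 9.86, 11.99 and 12.8 CPM after AHR siRNA. TCF21 stood at 19.3, 16.1, 17.7 and 17.8 CPM in the controls and at 3.10, 2.18, 2.78 and 2.65 CPM after TCF21 siRNA. AHR was also lower after TCF21 siRNA, at 47.0, 44.1, 44.6 and 46.5 CPM, whereas TCF21 after AHR siRNA stood at 18.7, 17.7, 17.7 and 19.5 CPM. In the overexpression experiment the scaled reads of AHR were 7324, 7407, 7054 and 6778 in the controls and 54083, 62871, 133840 and 81336 in the overexpressing libraries.

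**Figure D1:**
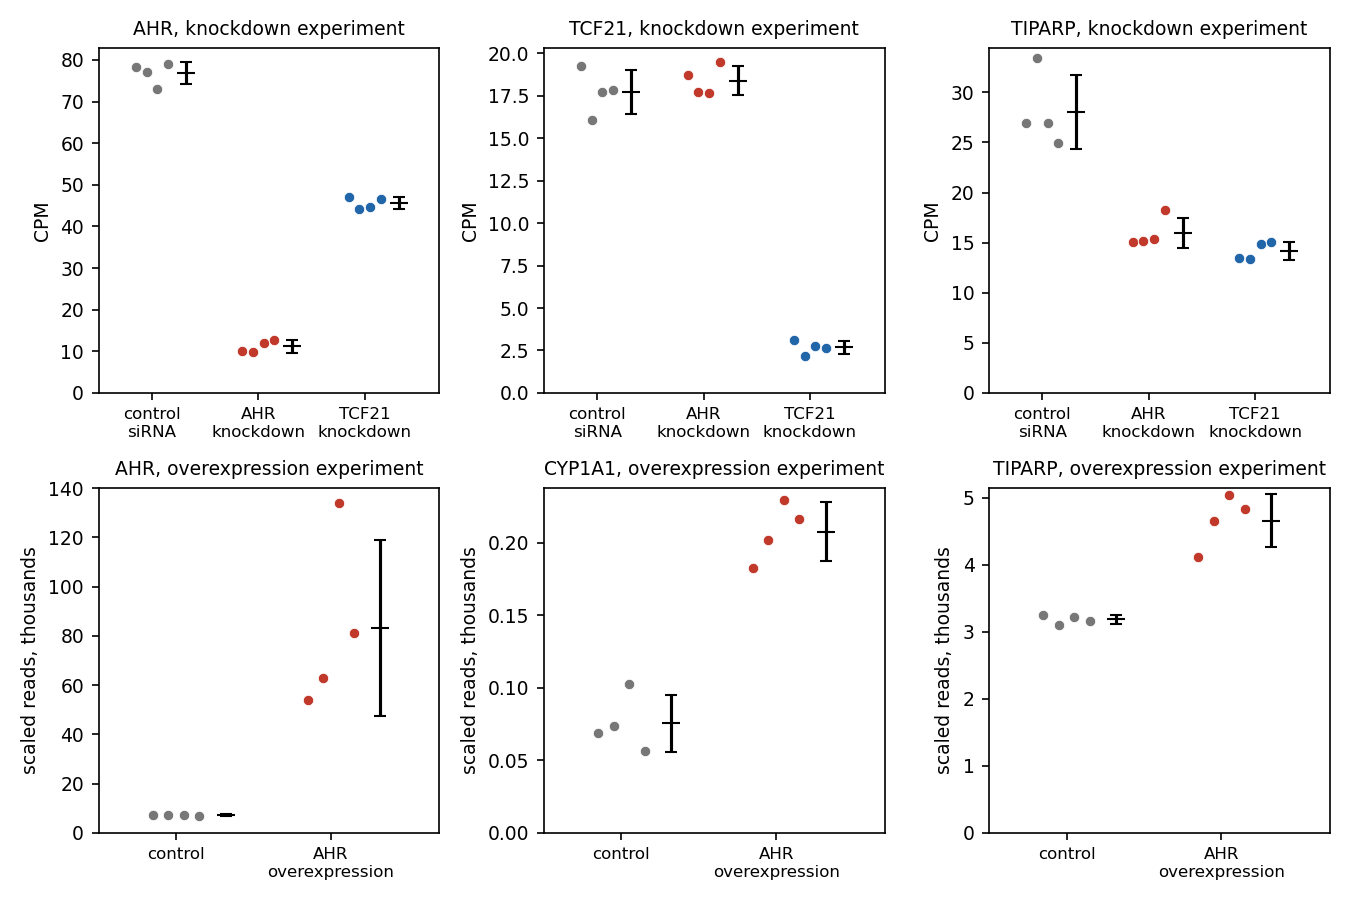
Levels of AHR, TCF21 and TIPARP in the 12 knockdown libraries (CPM) and of AHR, CYP1A1 and TIPARP in the 8 overexpression libraries (size-factor-scaled reads, axis in units of 1000); dots are libraries, bars are means and error bars are SD, n = 4 per group. AHR averaged 76.8 CPM in the controls, 11.2 CPM after AHR siRNA and 45.6 CPM after TCF21 siRNA.

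Knockdown of AHR lowered AHR from 76.8 ± 2.61 to 11.2 ± 1.46 CPM (SD, n = 4 each), a log2 change of −2.79 ± 0.07 (SE; adjusted p = 8.8e-17). PSAT1, an enzyme of serine synthesis, rose from 8.24 ± 0.78 to 75.5 ± 5.0 CPM (log2 3.20 ± 0.07, adjusted p = 1.7e-17). ZMAT3, a p53 target, rose from 23.4 ± 1.2 to 136 ± 15 CPM, and CHI3L1, a secreted glycoprotein, rose by a log2 change of 2.79 ± 0.12. The collagen-degrading protease MMP3 fell from 80.7 ± 17 to 8.64 ± 0.5 CPM (log2 −3.21 ± 0.11, adjusted p = 3.6e-15). CERKL, SCG2 and ARL6IP1 were the other large rises (2.55, 2.42 and 2.41), and MMP10, EHF, VIPR1 and RASD1 the other large falls (−3.07, −2.94, −2.71 and −2.39). MMP3 and MMP10 are related in sequence, so their separate values are uncertain.

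Among 9 measured genes of the AHR battery, 1 rose, 5 fell and 3 did not pass. CYP1B1, a xenobiotic-metabolising enzyme induced by AHR, fell from 26.6 to 12.8 CPM (log2 −1.06 ± 0.09, adjusted p = 3.2e-09). CYP1A1 fell by 2.18 ± 0.41 on the log2 scale from 1.11 ± 0.39 CPM, TIPARP by 0.82 ± 0.09, SERPINB2 by 1.88 ± 0.11 and STC2 by 0.81. The amino acid transporter SLC7A5 rose (0.36 ± 0.07), while NQO1 (0.04), ABCG2 (0.57) and NFE2L2 (0.11) did not pass. The list as a whole had a median of −0.81 and did not pass camera (adjusted p = 0.061, and 0.20 with an estimated correlation). At the preset correlation this list is on the edge: it passed without control replicate 3 or 4 or AHR siRNA replicate 1 or 2 (adjusted p = 0.04998, 0.041, 0.044 and 0.044). In the AHR complex list 1 of 9 members rose and 3 fell, the targeted AHR itself among them, with ARNT at −0.57 (list adjusted p = 0.64).

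The contractile list had 9 of 18 members higher and 4 lower after AHR knockdown. Myosin light chain kinase MYLK rose from 40.5 to 92.5 CPM (1.19 ± 0.05), smooth muscle actin ACTA2 from 275 to 448 CPM (0.71 ± 0.05), and LMOD1 by 0.75 ± 0.08. As a list it did not pass (median 0.21, adjusted p = 0.087, and 0.041 without control replicate 4). Modulated smooth muscle genes split, with 6 risen and 5 fallen of 14. LUM (−1.35 ± 0.10), KLF4 (−1.08) and DCN (−0.91) were among those that fell (list adjusted p = 0.80). Chondrogenic genes had 2 risen and 3 fallen of 12, with BMP2 lowered from 233 to 80.7 CPM (−1.53 ± 0.08), HAPLN1 at −0.82 and SOX9 at −0.43 (list adjusted p = 0.66). Matrix genes had 11 risen and 6 fallen of 21, or 12 and 6 adjusted over the list alone, with THBS2 at 1.41, COL3A1 at 0.45 and COL4A1 at −0.97 (adjusted p = 0.32). Matrix proteases had 5 risen and 6 fallen of 14, including MMP1 at −1.58 (list adjusted p = 0.091).

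Cell cycle genes rose after AHR knockdown: 17 of 28 rose and 1 fell, or 19 and 1 adjusted over the list alone, with a median of 0.60 (adjusted p = 0.00036, and adjusted p = 0.035 with an estimated correlation). TOP2A (1.32 ± 0.11), the proliferation marker MKI67 (1.05 ± 0.13) and the replication clamp PCNA (0.94 ± 0.07) were examples. Interferon response genes had 16 of 22 risen and 2 fallen, led by MX2 (1.97 ± 0.16), OAS2 (1.26 ± 0.12) and OAS3 (1.21 ± 0.15). Their adjusted p of 0.00036 became adjusted p = 0.49 with an estimated correlation. Sterol synthesis genes had 16 of 20 risen and none fallen, or 17 adjusted over the list alone, among them SC5D (1.76 ± 0.12), SCD (0.99 ± 0.05) and DHCR7 (0.50) (adjusted p = 8.5e-07, and adjusted p = 0.11 with an estimated correlation). In the immediate early list 9 of 16 fell and 0 rose, with the flow-responsive factor KLF2 at −1.55 ± 0.11, DUSP1 at −0.66 and FOSL1 at −0.57 (adjusted p = 0.0018, and adjusted p = 0.29 with an estimated correlation).

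Other lists did not pass as a whole after AHR knockdown. In the TGF-beta list 5 of 15 rose and 4 fell, with TGFB1 at 1.03 and TGFBI at −0.64 (adjusted p = 0.93). Inflammatory cytokine genes had 6 risen and 13 fallen of 24, or 7 and 13 adjusted over the list alone, with PTGS2 at 1.31, ICAM1 at 0.95 and IL1B at −1.17 (adjusted p = 0.086). NRF2 genes had 4 risen and 4 fallen of 16, with AKR1B10 at 1.24, GCLC at 0.87 and ME1 at 0.65 (adjusted p = 0.79). Stress genes of the unfolded protein list had 7 risen and 3 fallen of 15, with HSPA5 at 0.53 and PPP1R15A at −0.45 (adjusted p = 0.26). Hypoxia genes had 3 risen and 6 fallen of 14, with P4HA1 at 0.44, PGK1 at −0.38 and VEGFA at −0.26 (adjusted p = 0.80). Of 25 coronary disease locus genes, 10 rose and 4 fell. PDGFRB, a growth factor receptor, rose from 22.5 to 89.1 CPM (1.98 ± 0.07), CNNM2 by 1.12 and JCAD by 0.89 (list adjusted p = 0.086). Markers of other cell types moved both ways. Among them were endothelial TIE1 at 1.78, ROBO4 at −1.04 and CDH5 at −0.98 (3 risen, 3 fallen of 9; adjusted p = 0.99), leukocyte CD14 at 1.61 (1 of 5 risen; adjusted p = 0.26), fibroblast SCARA5 at −1.45 with CD248 at 0.49 (3 and 3 of 9; adjusted p = 0.84), and pericyte CSPG4 at 1.29 with NOTCH3 at 1.23 (2 of 5 risen; adjusted p = 0.091). The median lay above 0 and the test pointed down for the AHR complex, modulated, chondrogenic and endothelial lists, and the reverse held for the NRF2 list. Mean and median differed in sign for the AHR complex, chondrogenic, NRF2, hypoxia and fibroblast lists. Adjusted over the list alone, 5 NRF2 genes rose and 4 fell, as did 10 and 5 coronary locus genes, and the counts stayed as given where no second count is printed. The inflammatory and coronary locus lists passed at the preset correlation without control replicate 4 (adjusted p = 0.041 each). In all, edgeR called 5510 of 13767 genes, 2798 higher and 2712 lower, of which 476 and 223 changed more than 2-fold.

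Knockdown of TCF21 lowered TCF21 from 17.7 ± 1.3 to 2.68 ± 0.38 CPM (log2 −2.73 ± 0.10, adjusted p = 1.8e-14) and AHR to 45.6 ± 1.4 CPM (−0.75 ± 0.07, adjusted p = 9.2e-09). Thioredoxin reductase TXNRD1 fell from 1515 to 555 CPM (−1.45 ± 0.04, adjusted p = 1.4e-15) and the quinone reductase NQO1 from 267 to 105 CPM (−1.35 ± 0.05, adjusted p = 6.8e-15). The eosinophil chemokine CCL11 fell from 7.42 to 1.04 CPM (−2.83 ± 0.15), SERPINB2 by 2.55 ± 0.11 and the cystine transporter SLC7A11 by 1.79 ± 0.06. COL22A1 rose from 21.2 to 106 CPM (2.32), next to ARL6IP1 (2.73 ± 0.08), DCHS1 (2.72 ± 0.15), SESN3 (2.40), CERKL (2.39) and PSAT1 (2.29). AKR1B10 (−1.97), IL24 (−1.95) and AKR1C2 (−1.85) completed the largest falls. The AKR1 genes are close paralogs whose separate values are uncertain.

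The NRF2 response, the antioxidant programme to which NQO1 and TXNRD1 belong, had 14 of 16 members lowered and 1 raised by TCF21 knockdown, with a median of −0.99 (adjusted p = 7.2e-10, and adjusted p = 0.0029 with an estimated correlation). All 14 measured hypoxia genes rose, with BNIP3 at 0.85 ± 0.06, NDRG1 at 0.79 ± 0.05 and the glucose transporter SLC2A1 at 0.60 ± 0.05 (median 0.55, adjusted p = 7.5e-07, and adjusted p = 0.065 with an estimated correlation). In the AHR battery 6 of 9 genes fell and 2 rose. NFE2L2 (−0.87), TIPARP (−0.99), SLC7A5 (−0.52) and STC2 (−0.34) fell, CYP1B1 (0.53 ± 0.08) and ABCG2 (1.13) rose, and CYP1A1 at −0.58 ± 0.36 did not pass (list adjusted p = 0.0034, and adjusted p = 0.065 with an estimated correlation). The AHR complex list had 3 risen and 3 fallen of 9, with ARNT at −0.92 (adjusted p = 0.34).

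Contractile genes had 11 of 18 risen and 1 fallen, with SYNPO2 at 1.26, MYLK at 0.90 and CALD1 at −0.45 (adjusted p = 0.0038, and adjusted p = 0.21 with an estimated correlation). Matrix genes had 12 of 21 risen and 2 fallen, or 15 and 3 adjusted over the list alone, with THBS2 at 1.13, FBN1 at 0.86 and COL8A1 at −0.73 (adjusted p = 0.0019, and adjusted p = 0.21 with an estimated correlation). Interferon genes had 12 of 22 risen and 2 fallen, or 15 and 2 adjusted over the list alone, with MX2 at 1.91, OAS2 at 1.23 and IFIT3 at 1.10 (adjusted p = 0.0077, and adjusted p = 0.50 with an estimated correlation). Cell cycle genes had 15 of 28 risen and 3 fallen, with TOP2A at 0.78, PCNA at 0.73 and MCM7 at −0.41 (adjusted p = 0.017, and adjusted p = 0.082 with an estimated correlation). Sterol genes had 12 of 20 risen and 0 fallen, or 13 and 1 adjusted over the list alone, with SC5D at 2.06 and SCD at 0.94 (adjusted p = 0.0013, and adjusted p = 0.19 with an estimated correlation). Pericyte genes had 3 of 5 risen, with CSPG4 at 1.42, NOTCH3 at 0.80 and KCNJ8 at 0.66 (adjusted p = 0.045, and adjusted p = 0.19 with an estimated correlation). That list also did not pass with the replicate block (adjusted p = 0.056) or without control replicate 3 or 4, AHR siRNA replicate 3 or 4 or TCF21 siRNA replicate 4 (0.05039, 0.068, 0.05035, 0.052 and 0.053).

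The remaining lists did not pass after TCF21 knockdown. Modulated genes had 4 risen and 7 fallen of 14, or 4 and 8 adjusted over the list alone, with DCN at −1.15 and FN1 at 0.42 (adjusted p = 0.12). The targeted TCF21 itself is among those fallen. Chondrogenic genes had 5 risen and 4 fallen of 12, with MATN3 at 1.22, HAPLN1 at −0.92 and SOX9 at −0.66 (adjusted p = 0.92). Proteases had 6 risen and 8 fallen of 14, with the inhibitor TIMP3 at 1.51, MMP3 at −1.77 and ADAMTS1 at −1.01 (adjusted p = 0.38). The TGF-beta list had 7 risen and 3 fallen of 15, or 7 and 4 adjusted over the list alone, with the BMP targets ID1 at 1.88, ID3 at 1.35 and BAMBI at 0.90 (adjusted p = 0.23). Inflammatory genes had 7 risen and 9 fallen of 24, with PTGS2 at 1.11 and CXCL3 at −1.26 (adjusted p = 0.45). Unfolded protein genes had 5 risen and 3 fallen of 15, with CHAC1 at 0.80 and HSPA5 at 0.62 (adjusted p = 0.41). The immediate early list had 3 risen and 7 fallen of 16, with KLF2 at −1.29, EGR2 at −1.06 and KLF6 at 0.34 (adjusted p = 0.23). Coronary locus genes had 11 risen and 5 fallen of 25, with PDGFRB at 1.47, CNNM2 at 0.94 and CDKN2B at 0.77 (adjusted p = 0.13). The endothelial (4 risen, 1 fallen of 9, TIE1 at 1.94; adjusted p = 0.13), leukocyte (1 of 5 risen, CD14 at 1.97; adjusted p = 0.23) and fibroblast lists (2 risen, 3 fallen of 9, SCARA5 at −1.31; adjusted p = 0.94) did not pass either. Median and test differed in sign for the chondrogenic, unfolded protein and fibroblast lists, and mean and median for the protease and unfolded protein lists. Adjusted over the list alone, the inflammatory genes had 7 risen and 10 fallen, unfolded protein genes 6 and 3, immediate early genes 4 and 7, coronary locus genes 11 and 6, endothelial genes 5 and 1 and fibroblast genes 3 and 3. edgeR called 5965 of 13767 genes, 3120 higher and 2845 lower, with 624 and 155 past 2-fold.

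**Figure D2:**
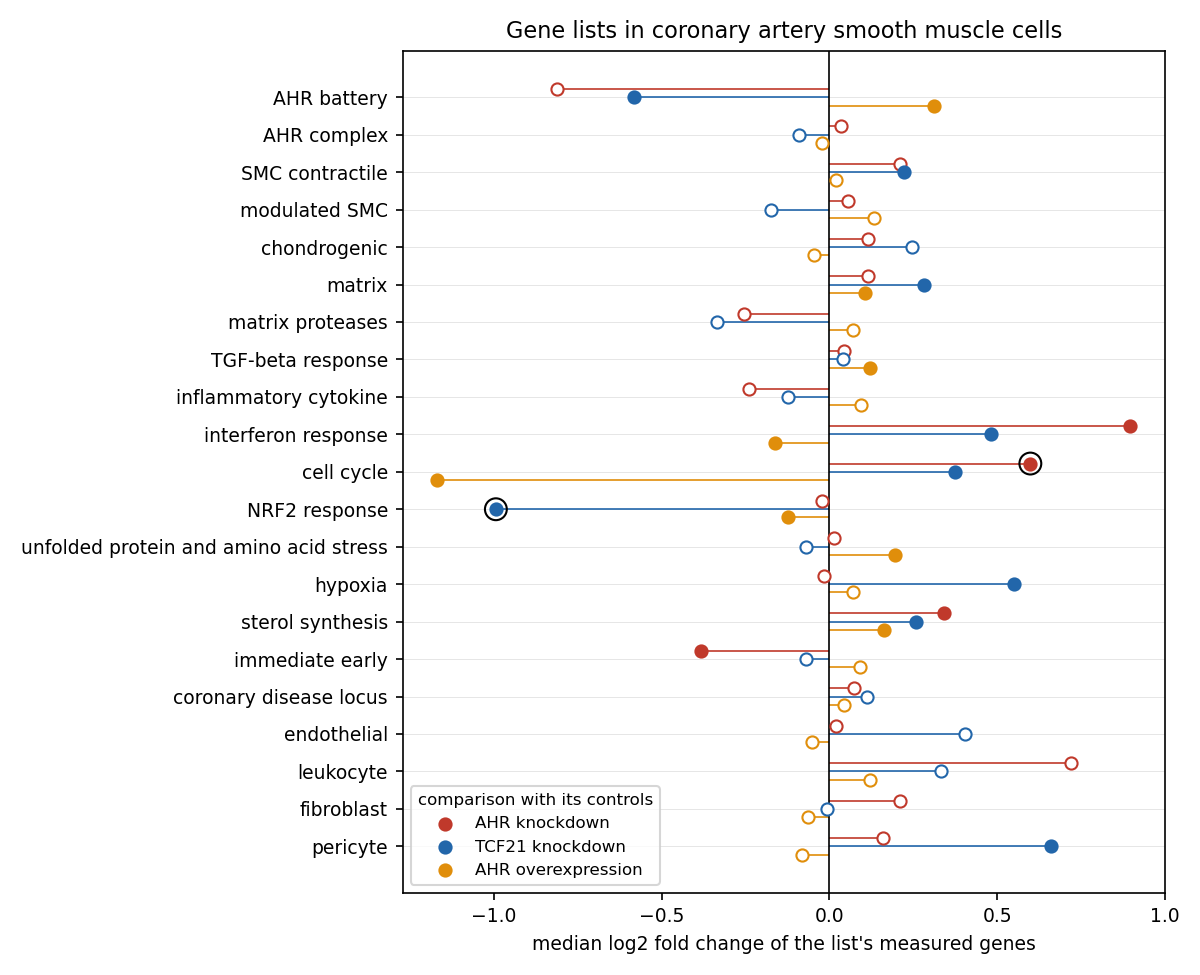
Median log2 change of 21 gene lists after AHR knockdown, TCF21 knockdown and AHR overexpression (n = 4 libraries per group); filled points have an adjusted p under 0.05 at the preset correlation and black rings also with an estimated correlation. Rings mark the cell cycle list after AHR knockdown (median 0.60) and the NRF2 list after TCF21 knockdown (median −0.99).

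Set directly against each other, the AHR and TCF21 knockdowns differed most in the NRF2 list, with all 16 measured members higher after AHR knockdown (median 0.97, adjusted p = 1.8e-14, and adjusted p = 0.00073 with an estimated correlation). AKR1B10 stood at 39.4 CPM after AHR knockdown and 4.23 CPM after TCF21 knockdown (log2 3.22 ± 0.09), CCL11 at 10.2 and 1.04 CPM (3.28 ± 0.14), and NQO1 differed by 1.39. Hypoxia genes were lower in 13 of 14 (median −0.53, adjusted p = 7.3e-09, and adjusted p = 0.048 with an estimated correlation), among them PGK1 at −0.78. Proteases were lower in 9 of 14 and higher in 2, with MMP3 at −1.44 and TIMP3 at −1.30 (adjusted p = 0.038, and adjusted p = 0.24 with an estimated correlation). The protease list also did not pass with the replicate block (adjusted p = 0.055) or without control replicate 1, AHR siRNA replicate 1 or 4 or TCF21 siRNA replicate 3 (0.052, 0.067, 0.083 and 0.054). MGP (1.61), SCG2 (2.27), ADAMTS14 (2.19) and CCN4 (1.99) were higher after AHR knockdown, whereas TULP3 (−2.19 ± 0.07), PODXL (−1.95), ID1 (−1.84), CYP1B1 (−1.59), COL4A1 (−1.50) and BMP2 (−1.15) were lower. edgeR called 4825 genes in this contrast, 2234 higher and 2591 lower after AHR knockdown, and the other 18 lists did not pass, though immediate early genes did without TCF21 siRNA replicate 2 (adjusted p = 0.048). Mean and median differed in sign for the AHR battery, AHR complex, modulated, leukocyte and fibroblast lists.

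Many genes moved the same way in both knockdowns. CPXM1 (6.65 after AHR and 8.13 after TCF21 knockdown), PCDHAC2 (4.74 and 4.82), MMP9 (3.29 and 5.54), FAIM2 (5.06 and 3.08) and TMEM130 (2.97 and 3.36) rose in both. WTAPP1 (−3.03 and −3.52), KRTAP2-3 (−2.76 and −2.48), IL19 (−2.59 and −2.43), CCK (−2.88 and −2.02) and SPINT1 (−3.01 and −2.0) fell in both. In all 1768 genes rose in both and 1354 fell in both, where independent lists give 634.1 and 560.4. Opposite moves counted 129 and 204 genes, against 578.2 and 614.6. The knockdowns share their control libraries. Simulated unchanged groups gave 0 shared calls on average over 20 simulations. At most 2 genes were called for AHR in any of them, so shared calls could hardly arise. These simulations do not show how shared controls add to an overlap of many called genes. Comparisons with the controls divided between the knockdowns gave 2252 and 1936 shared genes, where independent lists give 796.9 and 623.7. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.6604 and a Spearman correlation of 0.5936, against 0.5034 and 0.4572 simulated from shared controls alone. With split controls the Pearson correlations were 0.5467 and 0.5591. The covariance was 0.1741 against 0.0137 simulated, a difference of 0.1604.

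Overexpression raised AHR from 7141 ± 285 to 83033 ± 35725 scaled reads (log2 3.45 ± 0.19, SE; adjusted p = 6.5e-07; n = 4 each). CYP1A1 rose from 75.3 ± 19 to 208 ± 20 scaled reads (1.48 ± 0.17, adjusted p = 4.9e-04) and TIPARP, a feedback repressor of AHR, from 3185 ± 64 to 4659 ± 394 (0.54 ± 0.06, adjusted p = 3.9e-04). Among the largest rises were CLDN14 (1.49 ± 0.21), the cytokine IL11 (1.15 ± 0.11), COL7A1 (1.13 ± 0.11), NFATC2 (1.13 ± 0.13) and the prostaglandin synthase PTGS2 (1.09 ± 0.09). The largest falls were of mitotic genes, DLGAP5 (−1.95 ± 0.41), AURKB (−1.87), IQGAP3 (−1.79), PBK (−1.77), CENPF (−1.76) and TOP2A (−1.75 ± 0.38, adjusted p = 0.018). TCF21 was lower by a log2 change of −0.31 ± 0.07 (adjusted p = 0.025).

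In the AHR battery 6 of 10 genes rose and 0 fell, or 6 and 1 adjusted over the list alone, with AHRR at 0.36, CYP1B1 at 0.32, STC2 at 0.31 and SLC7A5 at 0.21 besides CYP1A1 and TIPARP. SERPINB2 (0.39), ABCG2 (0.19), NFE2L2 (−0.03) and NQO1 (−0.19) did not pass (list median 0.31, adjusted p = 1.1e-05, and adjusted p = 0.056 with an estimated correlation). Cell cycle genes had 25 of 29 fallen and 0 risen, or 29 fallen adjusted over the list alone, with a median of −1.17 and CCNB2 at −1.37, TYMS at −0.72 and TPX2 at −0.52 (adjusted p = 5.1e-19, and adjusted p = 0.21 with an estimated correlation). Overexpression replicate 3 stood apart from the other libraries, with the most AHR reads of the 8. TOP2A was 288 there against 1437, 1538 and 1021 in the other overexpressing libraries and 3482, 3329, 2802 and 2583 in the controls. Without that library 989 genes were called.

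Interferon genes had 5 of 20 fallen and 0 risen, with IFIT1 at −0.86, OAS1 at −0.67 and OAS3 at −0.59 (adjusted p = 3.6e-05, and adjusted p = 0.18 with an estimated correlation). Matrix genes had 4 of 20 risen, or 7 adjusted over the list alone, with COL6A3 and VCAN at 0.29 and COL5A1 at 0.25 (adjusted p = 9.2e-06, and adjusted p = 0.19 with an estimated correlation). The TGF-beta list had 6 risen and 2 fallen of 16, or 8 and 2 adjusted over the list alone, with PMEPA1 at 0.93, TGFBI at 0.44 and SMAD7 at 0.35 (adjusted p = 0.0017, and adjusted p = 0.064 with an estimated correlation). NRF2 genes had 1 risen and 4 fallen of 16, or 1 and 6 adjusted over the list alone, with TXNRD1 at −0.47, TXN at −0.29 and HMOX1 at 0.25 (adjusted p = 0.0025, and adjusted p = 0.064 with an estimated correlation). Unfolded protein genes had 4 of 15 risen, or 6 adjusted over the list alone, with DNAJB9 at 0.37, PPP1R15A at 0.24 and HSPA5 at 0.23 (adjusted p = 9.2e-06, and adjusted p = 0.32 with an estimated correlation). Sterol genes had 3 of 20 risen, or 12 risen and 1 fallen adjusted over the list alone, with INSIG1 at 0.63, MVD at 0.31 and SQLE at 0.28 (adjusted p = 9.2e-06, and adjusted p = 0.056 with an estimated correlation).

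Contractile genes showed no call among 19 measured by limma over all genes, and 1 risen and 1 fallen adjusted over the list alone. The most abundant, TAGLN, stood at 0.02 (list adjusted p = 0.60). The AHR complex (2 of 9 risen, the overexpressed AHR itself and ARNTL at 0.29, list adjusted p = 0.31) and modulated lists (1 risen, 1 fallen of 13, KLF4 at 0.24, list adjusted p = 0.32) did not pass. Nor did the chondrogenic list (1 of 14 risen, BMP2 at 0.74 ± 0.07, list adjusted p = 0.67). Proteases (2 of 12 risen, MMP10 at 0.69 and ADAMTS4 at 0.56, list adjusted p = 0.060) did not pass as a list. Inflammatory genes (5 risen, 1 fallen of 24, LIF at 0.65 and IL1B at 0.60, list adjusted p = 0.31) did not pass as a list. The hypoxia (3 of 14 risen, VEGFA at 0.36; adjusted p = 0.073), immediate early (2 of 17 risen, NR4A1 at 0.65; adjusted p = 0.33), coronary locus (3 risen, 2 fallen of 25, CDKN2B at 0.53; adjusted p = 0.20) and pericyte lists (1 of 6 risen, NDUFA4L2 at 0.42; adjusted p = 0.60) did not pass either. At the preset correlation the proteases were on the edge: they passed with the replicate block (adjusted p = 0.024) and without control replicate 3 or overexpression replicate 1 or 3 (0.040, 0.021 and 0.032). The coronary locus and hypoxia lists passed without overexpression replicate 3 (0.033 and 0.039). No endothelial, fibroblast or leukocyte marker was called by limma (adjusted p = 0.47, 0.31 and 0.31 for the lists), with TEK at −0.05, PDGFRA at −0.07 and CD14 at 0.24. Median and test differed in sign for the AHR complex and chondrogenic lists, and mean and median for the AHR complex list. Adjusted over the list alone, modulated genes had 3 risen and 3 fallen, proteases 3 and 0, inflammatory genes 7 and 4, immediate early genes 4 and 3, coronary locus genes 7 and 5, pericyte genes 1 and 2, endothelial and fibroblast genes 0 and 2 each, and leukocyte genes 1 and 0.

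limma called 739 of 15682 genes after AHR overexpression, 308 higher and 431 lower, with 17 and 101 past 2-fold. The number fell to 177, 224, 351 and 415 without control replicate 1, 2, 3 or 4 and to 395 without overexpression replicate 4, while DESeq2 on the recovered reads called 1164 and edgeR 777. Of 13773 genes with an adjusted p in the authors' deposited table, 1128 passed the same threshold, 511 higher and 617 lower in the overexpressing cells.

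Some genes moved in opposite directions on loss and gain of AHR, mitotic genes among them. HMMR (2.07 after knockdown and −1.74 after overexpression), NUF2 (1.46 and −1.68), NCAPH (1.78 and −1.44), PBK (1.37 and −1.77) and TOP2A (1.32 and −1.75) rose on knockdown and fell on overexpression. Besides AHR itself, CYP1A1 (−2.18 and 1.48), FGD4 (−1.16 and 0.91) and GDF6 (−1.18 and 0.86) went the other way. Of 12320 genes tested in both, 154 rose on knockdown and fell on overexpression, where independent lists give 85.8 (Fisher's exact p = 4.33e-15), and 116 did the reverse, against 58.2 (Fisher's exact p = 3.97e-15). Genes that rose in both numbered 65 against 60.1 (Fisher's exact p = 0.464), and genes that fell in both 49 against 83 (Fisher's exact p = 8.37e-06). These p-values treat genes as independent, which they are not. The opposite total fell to 82, 97, 150 and 162 without overexpression control replicate 1, 2, 3 or 4 and to 155 without overexpression replicate 4. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of −0.1381 and a Spearman correlation of −0.0961.

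**Figure D3:**
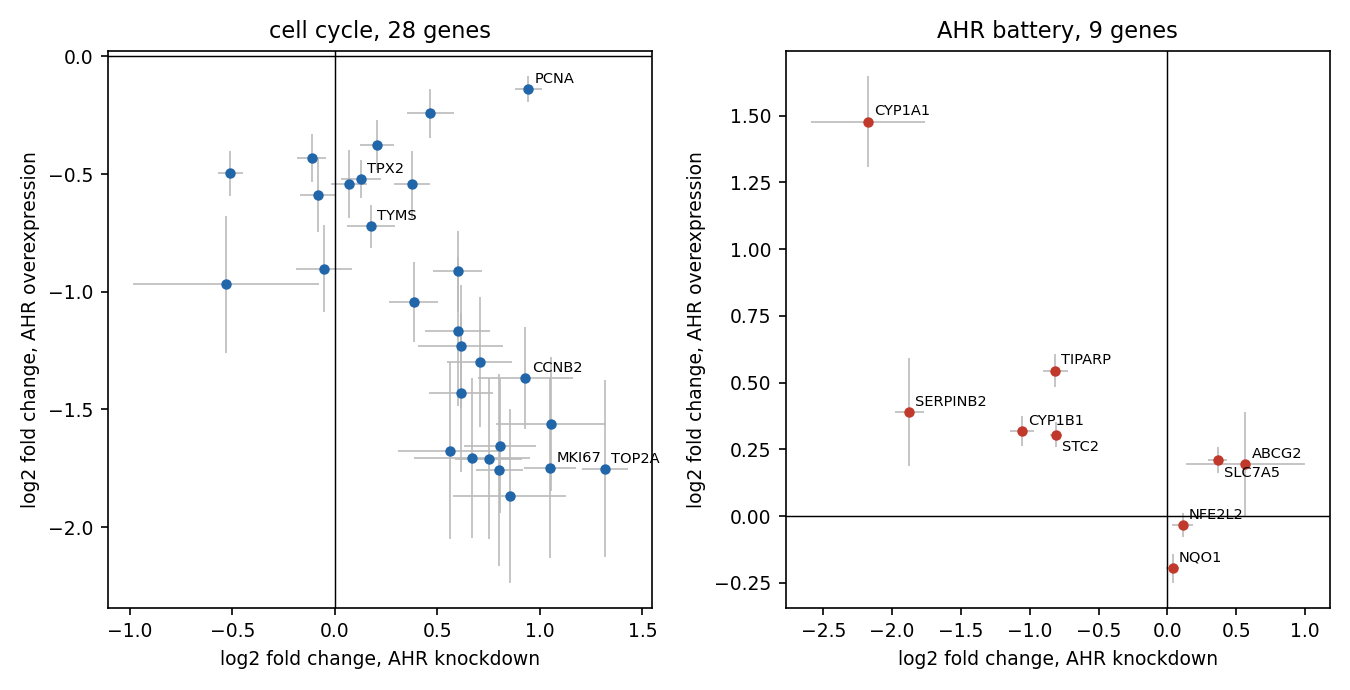
Log2 change after AHR knockdown (x axis) and after AHR overexpression (y axis) of 28 cell cycle genes and 9 AHR battery genes, with SE bars, n = 4 libraries per group. TOP2A lies at 1.32 and −1.75, and CYP1A1 at −2.18 and 1.48.

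In the mouse libraries, CMC cells (cluster 2, which carried chondrogenic markers) were 5.31% (95% exact Clopper-Pearson interval 4.28 to 6.49) and 5.15% (4.14 to 6.33) of wild-type cells. Knockout replicates 1, 2 and 3 had 86.15% (83.34 to 88.65), 17.35% (14.17 to 20.91) and 9.55% (6.63 to 13.22). The means were 5.23% ± 0.11 (SD, n = 2) and 37.68% ± 42.15 (n = 3), a difference of 32.45 points (exact two-sided permutation p = 0.5). Without knockout replicate 1 the difference was 8.22 points. In cells of 6000 to 12000 raw UMIs the CMC shares were 5.95% and 5.82% in wild-type and 86.48%, 9.5% and 5.08% in knockout libraries. That range kept 17 of 89 CMC and 108 of 263 SMC cells of knockout replicate 2. In knockout replicate 3 it kept 6 of 32 and 85 of 227. The range itself thus lowered the CMC shares of knockout replicates 2 and 3. SMC cells (clusters 0, 3, 4 and 5) were 71.91% and 71.88% in wild-type and 7.73%, 51.27% and 67.76% in knockout libraries, means of 71.9% and 42.25% (exact permutation p = 0.2). Among the 10 leading genes of cluster 1, the authors' FMC class, 2 were fibroblast markers and 1 was a marker of its own class. All 8 of its own markers were detected in it, with a mean log2 difference from all cells of 0.38. For fibroblast markers, 6 of 7 were detected, with 1.07. The share of this class was 18.96% and 19.27% in wild-type and 5.83%, 27.88% and 20.6% in knockout replicates 1, 2 and 3, means of 19.12% and 18.1% (exact permutation p = 1.0). The difference of −1.02 points was 5.12 without knockout replicate 1. Cluster 6, the authors' Pericyte class, was raised in both the pericyte and the endothelial marker sets. Their mean log2 differences from all cells were 2.57 and 2.70. The class averaged 2.8% in wild-type and 0.82% in knockout libraries (exact permutation p = 0.1). MP cells averaged 0.96% and 1.14% (exact permutation p = 0.9), with 0 of 686 in knockout replicate 1, which allows up to 0.437%. With 10 arrangements no exact p can lie below 0.1. The wild-type libraries resembled each other closely, with a Spearman correlation across genes of 0.9928, against 0.9176 to 0.9754 among the knockout libraries. Whether they came from separate animals was not examined. If not, their SD leaves out the spread between animals. The tdTomato and viability sort set which cells were counted, and the knockout cells were sequenced more deeply.

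**Figure D4:**
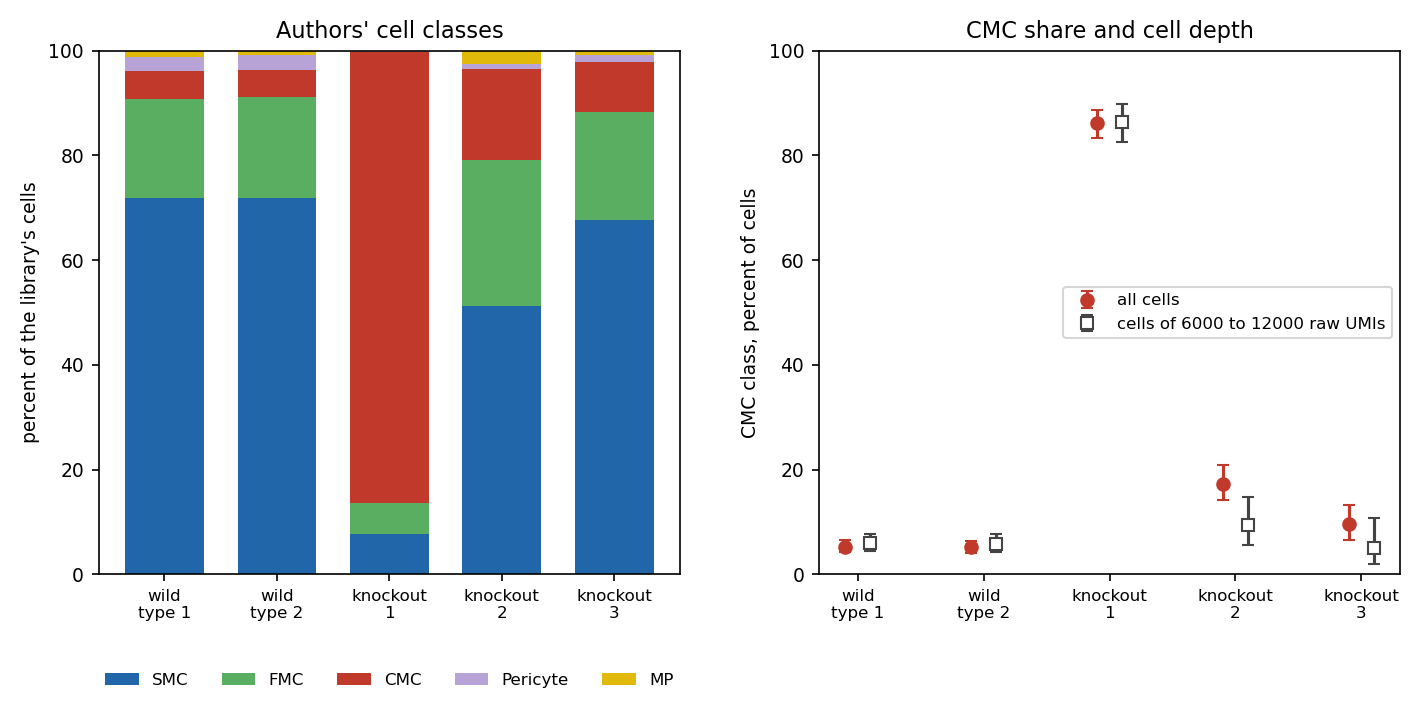
Share of the authors' cell classes per mouse library (percent of cells) and share of CMC cells in all cells and in cells of 6000 to 12000 raw UMIs, with 95% exact intervals; 2 wild-type and 3 knockout libraries. Knockout replicate 1 had 86.15% CMC cells and the other libraries 5.15% to 17.35%.

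Ahr transcripts averaged 0.0562 ± 0.016 corrected UMIs per SMC cell of the knockout libraries against 0.0117 ± 0.0034 in wild-type (log2 1.59 ± 0.38, adjusted p = 0.033). The log2 difference was 1.31 ± 0.20 over all cells, 1.22 ± 0.24 in cluster 1 (FMC) and −0.14 ± 0.41 in CMC cells, where means were 0.160 and 0.173, and none of these 3 passed. Per library over all cells, Ahr stood at 0.0513 and 0.0430 in wild-type and at 0.115, 0.162 and 0.122 in knockout replicates 1 to 3. Where the tags fall relative to a deleted part of Ahr was not examined. The higher Ahr in the knockout libraries therefore neither backs nor refutes their genotype labels. Over all cells the collagenase Mmp13 rose from 0.00302 ± 0.0017 to 0.338 ± 0.062 corrected UMIs per cell (4.73 ± 0.21, adjusted p = 0.011) and Mir143hg, the host transcript of a smooth muscle microRNA cluster, fell from 2.33 to 0.0773 (−4.77 ± 0.21, adjusted p = 0.011). These were the 2 genes limma called of 11059, with 3524 at an unadjusted p under 0.05. Without knockout replicate 1 the number was 5714, and it was 0 without wild-type replicate 1 or 2 or knockout replicate 2 and 1 without knockout replicate 3. Leaving out a wild-type library leaves 1, so the spread then comes from the knockout libraries alone. With the replicate block, or in cells of 6000 to 12000 raw UMIs, 0 genes were called over all cells. At a pseudocount of 0.1 the call of Mmp13 was lost. The median log2 difference of all tested genes was 0.378 over all cells, so list tests here are relative to that shift. At the preset correlation the contractile (median −1.07, adjusted p = 1.2e-11), pericyte (−0.55, adjusted p = 0.00029) and endothelial lists (−0.50, adjusted p = 0.0077) were lower and the sterol (0.86, adjusted p = 0.0027) and immediate early lists (1.12, adjusted p = 0.0027) higher over all cells. With an estimated correlation the adjusted p was 0.55, 0.48, 0.55, 0.55 and 0.55. Knockout replicate 1 held 7.73% SMC and 86.15% CMC cells. Acta2 stood at 17.3 corrected UMIs per cell there, at 139.5 and 139.99 in the other knockout libraries and at 135.9 and 138.7 in wild-type. At the preset correlation without that library, the endothelial and immediate early lists no longer passed (adjusted p = 0.066 and 0.061), while the contractile and pericyte lists still did. The chondrogenic list had a median of 1.69 (adjusted p = 0.75, and 0.94 with an estimated correlation). At the preset correlation it passed with the replicate block (adjusted p = 2.3e-10) and without knockout replicate 3 (0.00030). The modulated list (median 1.31, adjusted p = 0.093, and 0.61 with an estimated correlation) passed with the block (0.00060), with the same total per library (0.038) and without wild-type replicate 1 or 2 or knockout replicate 3 (0.048, 0.025 and 0.010). Other lists passed in single settings: unfolded protein with the block (0.019), cell cycle and interferon without wild-type replicate 2 (0.025 each), TGF-beta without knockout replicate 1 (0.049), and leukocyte and matrix without knockout replicate 2 (0.030 and 0.025). Adjusted over the list alone, 12 of 16 sterol and 9 of 17 immediate early genes rose, and no gene of the contractile, pericyte or endothelial lists was called by limma.

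Within SMC cells the repressor Nfil3 rose from 0.0243 to 0.442 corrected UMIs per cell (3.67 ± 0.31, adjusted p = 0.021) and the circadian output factor Dbp fell from 1.79 to 0.397 (−2.19 ± 0.24, adjusted p = 0.021). Ly6a (3.07), the stress factor Atf3 (3.03), Nr4a1 (2.62) and Arntl (2.06) rose, as did AY036118 (4.35 ± 0.35), Gm10269 (3.77) and Rpl10-ps3 (2.85), which are predicted or pseudogene-like loci that can share reads with other copies. Mir143hg (−4.21), Per3 (−1.85 ± 0.34), the heat shock protein Hspb1 (−1.56 ± 0.18), Gm26917 (−1.54) and Tcap (−1.46) fell. Of the AHR battery 1 of 8 rose, Nfe2l2 at 0.64, while Tiparp at 0.98 and Cyp1b1 at −0.04 did not pass (list adjusted p = 0.72). Chondrogenic genes had 3 risen and 1 fallen of 18, with Alpl at 1.25, Sox6 at 1.23, Sox9 at 1.08 and Acan at −0.98 (median 0.89 with the test pointing down, adjusted p = 0.51). These are low values to which free RNA of CMC cells can add. Alpl in SMC cells was 0.92% to 7.69% of its CMC level by library, Sox9 3.08% to 8.46% and Acan 1.02% to 3.12%. The abundant CMC gene Ibsp was 0.07% and 0.13% in wild-type and 1.05%, 0.14% and 0.24% in knockout replicates 1, 2 and 3. Free RNA adding an equal percent of each CMC gene would not give the Sox9 values as well. In knockout replicate 1 Alpl, at 1.62%, was close to Ibsp. In knockout replicate 1 the CMC genes Cytl1 and Comp had a UMI in 66.04% and 62.26% of SMC cells. In SMC cells of 6000 to 12000 raw UMIs, Sox6 stood at −0.33 and did not pass. Without knockout replicate 1 the chondrogenic and interferon lists gave adjusted p = 0.0074 each at the preset correlation.

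Contractile genes in SMC had 1 risen and 1 fallen of 21, Srf at 0.58 and Ldb3 at −0.62, and the list lay below the other genes (median 0.05, adjusted p = 3.6e-06, and adjusted p = 0.74 with an estimated correlation). Matrix genes had 2 risen and 1 fallen of 21, with Thbs2 at 0.75, Eln at 0.63 and Vcan at −0.77 (median −0.07, adjusted p = 3.6e-06, and adjusted p = 0.55 with an estimated correlation). The TGF-beta list had 3 risen and 2 fallen of 16, with Bambi at 1.29, Ctgf at 0.90 and Smad7 at −1.14 (adjusted p = 0.0012, and adjusted p = 0.53 with an estimated correlation), and the pericyte list 1 risen and 1 fallen of 6, Kcnj8 at 0.89 and Rgs5 at −0.95 (adjusted p = 0.019, and adjusted p = 0.55 with an estimated correlation). The pericyte list did not pass without knockout replicate 2 or 3 (adjusted p = 0.11 and 0.12), and neither it nor the TGF-beta list passed with the replicate block (0.072 each). Immediate early genes had 4 of 18 risen, including Nr4a2 at 1.76 and Dusp1 at 1.13, and sterol genes 4 of 15, including Lss at 1.46. Adjusted over the list alone, matrix genes had 0 risen and 1 fallen, TGF-beta genes 4 and 3, pericyte genes 1 and 2, immediate early genes 5 and 0 and sterol genes 6 and 0. Mean and median differed in sign for the contractile, TGF-beta and pericyte lists. Among the called members of other lists were the cytokine gene Ptgs2 (2.04), the interferon gene Isg20 (1.46), the protease Mmp3 (1.39), the modulated marker Klf4 (1.37), the hypoxia gene Adm (1.36), the NRF2 genes Pir (1.39) and Hmox1 (1.26), the cell cycle gene Mcm3 (1.21), Shmt2 (0.93) of the stress list, Ptges3 (−0.46) of the AHR complex list, Mras (1.08) of the coronary list and the fibroblast marker Dpt (1.81). Of all tested genes 22.3% were called, and 97.2% of those were higher.

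limma called 2360 of 10601 genes in SMC cells, 2295 higher and 65 lower in the knockout libraries. The median log2 difference of all tested genes was 0.471, so list tests here are relative to that shift. With means scaled to the same total per library the median was 0.319 and the calls 310 higher and 46 lower. No gene was called by limma without wild-type replicate 1 or 2 or knockout replicate 2 or 3, and 6350 were called without knockout replicate 1. In SMC cells of 6000 to 12000 raw UMIs, 6 genes were called. Genotype and lane cannot be told apart, since the wild-type libraries share 1 lane number and the knockout libraries used others.

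In cluster 1 (FMC) limma called 8 of 10943 genes, with 1940 at an unadjusted p under 0.05. Nfil3 rose from 0.0582 to 0.511 corrected UMIs per cell (2.92 ± 0.25, adjusted p = 0.014), next to AY036118 (4.13), Rps18-ps3 (2.39), the stress cytokine Gdf15 (2.11), Gm42418 (2.08) and Gm9493 (1.63), while Tcap (−2.79) and glutamine synthetase Glul (−1.75) fell. The median log2 difference of all tested genes was 0.284 in this class, and list tests are relative to it. The contractile list was lower, with 5 of 21 fallen adjusted over the list alone (median −0.30, adjusted p = 1.9e-09, and adjusted p = 0.95 with an estimated correlation). The immediate early list (adjusted p = 0.091) passed with the same total per library (0.026) and without wild-type replicate 1 or 2 or knockout replicate 1 (0.044, 0.045 and 3.5e-06). The interferon list (0.35) passed with the replicate block (0.029) and without knockout replicate 3 (0.016). No gene was called by limma without wild-type replicate 1 or 2 or knockout replicate 3, 1 without knockout replicate 2, and 213 without knockout replicate 1.

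In CMC cells limma called 6 of 10915 genes, all higher, with 802 at an unadjusted p under 0.05. The median log2 difference of all tested genes was 0.114 there. The nuclear receptor Nr4a1 rose from 0.138 to 1.98 corrected UMIs per cell (3.71 ± 0.30, adjusted p = 0.0022), and Atf3 (5.17 ± 0.67), Csrnp1 (4.00), AY036118 (3.62), Klf2 (1.99) and Bhlhe40 (1.71) rose too. Immediate early genes had 2 of 18 risen, or 15 adjusted over the list alone (median 1.58, adjusted p = 9.8e-12, and adjusted p = 0.20 with an estimated correlation). The chondrogenic genes Sox9 (0.81), Col2a1 (−1.12) and Ibsp (−0.18) did not pass (list median −0.07, adjusted p = 0.36, and adjusted p = 0.93 with an estimated correlation). At the preset correlation its direction changed with the library left out. It lay lower without knockout replicate 1 (adjusted p = 0.018) or 2 (0.0090), and higher without knockout replicate 3 (0.0025). Without wild-type replicate 2 it lay lower (0.045), with 1 wild-type library left and the spread coming from the knockout libraries. Contractile (median −1.32, adjusted p = 2.4e-21), cell cycle (−1.22, adjusted p = 7.3e-08), pericyte (−0.77, adjusted p = 2.3e-05) and matrix lists (−0.32, adjusted p = 0.00025) were lower, and the sterol (1.07, adjusted p = 0.00018), interferon (0.73, adjusted p = 0.01) and unfolded protein lists (0.49, adjusted p = 0.028) higher. With an estimated correlation their adjusted p was 0.12, 0.12, 0.12, 0.46, 0.46, 0.46 and 0.46. Many cell cycle genes lay near the floor in CMC cells, such as Mki67 (0.017 corrected UMIs per cell), Top2a (0.012), Birc5 (0.038) and Cdk1 (0.051). The most abundant, Pcna, went against the list: 0.169 and 0.235 in wild-type and 0.259, 0.258 and 0.5 in knockout replicates 1, 2 and 3 (log2 0.67, not passing). A fall of proliferation genes therefore cannot be read from this list. Acta2, abundant in SMC cells, stood in CMC cells at 2.03, 4.35 and 5.97 in knockout replicates 1, 2 and 3, whose SMC shares were 7.73%, 51.27% and 67.76%, and at 5.42 and 6.76 in wild-type. Further contractile genes, chosen after their values were seen, were Tagln at 0.861, 1.00 and 1.375 against 2.54 and 3.11, and Myh11 at 0.142, 0.101 and 0.219 against 0.562 and 0.812. The interferon list did not pass with the replicate block (adjusted p = 0.12) or without wild-type replicate 2 or knockout replicate 3 (0.20 and 0.19), nor the sterol list without wild-type replicate 1 (0.056). The unfolded protein list did not pass without wild-type replicate 1 or knockout replicate 1 or 2 (0.084, 0.16 and 0.15). The inflammatory list (0.24) passed without wild-type replicate 2 (0.039). With the replicate block the chondrogenic list lay higher (0.0016). The count of called genes was 0 without wild-type replicate 1, 1 without wild-type replicate 2 or knockout replicate 2, 29 without knockout replicate 1 and 112 without knockout replicate 3.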

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

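The tests of the fall of AHR, of the control siRNA and of deeper sequencing were written before their results were seen; all other tests in this part, the splits of the libraries included, were chosen only after the result was seen.

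The knockdowns of AHR and TCF21 moved 3122 genes in the same direction. Chance values of the shared controls are argued against, since controls divided between the knockdowns still gave at least 1936 shared genes. The fall of AHR after TCF21 siRNA cannot account for the whole either: 51.7% of the shared genes changed by as much or more in the TCF21 knockdown, where AHR fell less. An effect of the control siRNA itself stays open. The level without siRNA was taken from the overexpression controls, a separate experiment with its own table and scaling. A median log2 shift of 0.145 was removed first. Of 263 shared genes up over 2-fold in both, 59.3% had such a level closer to the knockdown libraries, with 59.6% of 47 down and 53.2% of all genes. Experiment and siRNA differ together there, so these values cannot decide. An effect of the control siRNA could contribute, as could common targets of the factors.

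Knockout replicate 1 held 86.15% CMC cells. Depth of the cells is argued against by a share of 86.48% in cells of 6000 to 12000 raw UMIs. A lower yield of contractile cells alone is argued against too, because the library had 14.78 CMC cells per FMC cell and the highest other library 0.62. That ratio cannot test a loss that also took FMC cells, which were 5.83% there and 18.96% to 27.88% in the other libraries. Genotype, label and batch of this library cannot be told apart: the highest share in the other knockout libraries in that depth range was 9.5%, and 1 mouse library has lanes that carry both genotype labels. In all cells knockout replicates 2 and 3 had 17.35% and 9.55%. The depth range left out more of their CMC than of their SMC cells, so the 9.5% does not show that they lack a rise. A biological difference between animals may lie behind it and was not tested.

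Genes called in SMC cells were 97.2% higher in the knockout libraries. The excess is not due to predicted and pseudogene symbols, since 97.2% were higher with those left out (2187 higher and 62 lower). A different annotation or alignment of the knockout libraries is a candidate explanation for the largest changes: 27 of 54 genes past 4-fold had such symbols, an odds ratio of 22.03 (Fisher's exact p = 2.06e-22). Depth stays open, because the median log2 difference fell from 0.471 to 0.2 in cells of 6000 to 12000 raw UMIs. Ahr genotype stays open too, with 0 wild-type libraries on a lane number of a knockout library.

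Chance assignment of the libraries to groups is argued against for the counts of called genes, at the smallest share these splits allow. Nothing technical that goes with the groups is tested by this. AHR knockdown gave 5297 genes and the highest of the other splits 0, TCF21 knockdown 6025 and 0, the direct contrast 4615 and 0, and AHR overexpression 739 and 0, so 1 split, the real one, reached each count, of 34 splits in the knockdowns and 35 in overexpression. In the knockdowns the split that follows the set code could not be fitted beside that term. The other splits mix changed libraries into both arms.

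Single libraries lay far from the other 3 of their group for 17 of 298 groups looked at, where chance gives about 1 in 20 groups, or 14.9. The values give the gap as a share of the group's range. In the knockdown controls CALD1 was 1708 CPM in replicate 2 against 1534 to 1560 (0.853). After AHR siRNA, replicate 3 was highest for DCHS1 (7.78 against 6.74 to 6.91 CPM, 0.836), FOSL1 (58.9 against 51.4 to 51.7, 0.953) and KLF2 (29.6 against 20.7 to 22.1, 0.84). Replicate 2 was highest for ID3 (28.9 against 23.0 to 23.1 CPM, 0.986) and PODXL (12.8 against 10.3 to 10.6, 0.855), and replicate 4 for PTGS2 (512 against 437 to 447, 0.868) and TIPARP (18.2 against 15.1 to 15.3, 0.927). After TCF21 siRNA, replicate 1 was lowest for CCL11 (0.642 against 1.16 to 1.18 CPM, 0.959) and TULP3 (39.4 against 42.6 to 42.9, 0.894), replicate 2 highest for CYP1A1 (0.928 against 0.642 to 0.676, 0.881) and lowest for STC2 (506 against 531 to 535, 0.858), and replicate 3 lowest for OAS2 (20.9 against 27.7 to 29.1, 0.835). In scaled reads, overexpression control replicate 2 was lowest for BMP2 (3660 against 4011 to 4050, 0.9) and replicate 3 highest for TGFBI (280900 against 262000 to 264700, 0.857). Among overexpressing libraries, replicate 3 was highest for PMEPA1 (1339 against 755 to 837, 0.859) and replicate 1 lowest for STC2 (56990 against 59870 to 60340, 0.86). MP cells, which no gene test used, were 2.53% of knockout replicate 2 (95% exact interval 1.36 to 4.29), above the highest wild-type share of 1.19%. The interval of that wild-type share, 0.73 to 1.84, overlaps it. Knockout replicates 1 and 3 lay lower, at 0.0% and 0.9%.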

How the results depend on the processing

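Halved knockdown counts, edgeR or TMM on the recovered reads, same-total scaling, the pseudocount of 0.1 and the range of 6000 to 12000 raw UMIs were chosen after seeing the data; the other alternatives were planned. The knockdown counts stayed within 1.5 times under every alternative run: DESeq2 called 5705, 6171 and 5038 genes for AHR, TCF21 and their contrast. Leaving out single libraries gave 4772 to 5577, 5314 to 6406 and 4126 to 5010 genes, and 2720 to 3230 shared in the same direction. None of 71 named AHR knockdown calls was lost under any setting run, against 2 of 75 for TCF21, 4 of 71 for the contrast, 24 of 56 for overexpression and 59 of 59 in SMC cells. The cause of the moves below was not tested, except that fewer libraries or cells lower the power.

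DESeq2 called 1164 genes after overexpression. Leaving out single libraries gave 177 to 989 genes there (177, 224, 351 and 415 without control replicates 1 to 4 and 395 without overexpression replicate 4) and 82 to 347 genes opposite to knockdown (82, 97, 150 and 162, and 155). In mouse they gave 0 to 5714 genes over all cells, 0 to 6350 in SMC, 0 to 213 in FMC and 0 to 112 in CMC cells, each with the highest value without knockout replicate 1 except CMC, without replicate 3. With no low-value filter limma called 1048, 0 and 1 genes in SMC, FMC and CMC, and with the same total 356, 5 and 3. All cells gave 1 gene at a pseudocount of 0.1 and 0 in the depth range, where SMC gave 6.

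The replicate numbers do not pair the samples. Correlations of same-numbered libraries ran from −0.081 to 0.204 in the human experiments and were −0.042 and −0.098 in the mouse libraries, with 2 numbers in common, and not every human library correlated best with its own number. With the number as a replicate block, calls were 5688, 6127 and 5040 in the knockdowns, but 0 over all mouse cells, 944 in SMC, 186 in FMC and 210 in CMC, with 8, 2 and 2 lists passing over all cells, in SMC and in FMC. Under the block Bglap in CMC turned to 2.27 and the chondrogenic list in CMC to an adjusted p of 0.001603 in the other direction. Leaving out single libraries gave adjusted p values of 0.002459 to 0.8674 for the list chondrogenic, Ahr knockout, CMC class, reversed without knockout replicate 3.

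With an estimated correlation 1, 1 and 0 lists passed for AHR knockdown, TCF21 knockdown and overexpression and 0 over all mouse cells, in SMC, FMC and CMC. Leaving out libraries gave 4 to 8 lists for AHR knockdown (8 without control replicate 4), 8 to 9 for TCF21, 2 to 4 for the contrast, 8 to 11 for overexpression, 4 to 8 over all mouse cells (8 without wild-type replicate 2), 3 to 6 in SMC, 1 to 2 in FMC and 6 to 9 in CMC; the same total gave 2 in FMC. Sox6 in SMC turned to −0.33 in the depth range while the log2 difference of Tcf21, Ahr knockout, all cells ran from −0.53 to 0.90 with single libraries left out, the latter without knockout replicate 1. Differences in share ran from −42.4 to −12.38 points for SMC, −5.9 to 5.12 for FMC (the latter without knockout replicate 1) and 8.22 to 46.52 for CMC (the former without it). Among the other values, lists kept their call in 1734 cases, were weaker in 62 and stronger in 39, and named genes in 7281, 589 and 46. Mouse DESeq2, RLE factors and thinning were not run because the matrix is not raw counts, nor RLE on the overexpression values, which the authors' factors already scale, nor another clustering, since the authors' classes were used.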

Other observations

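All values in this part were looked at only after the results were seen, and no test was run on them beyond those named.

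Values of 17 clock genes, a set picked after some of them had been named, were looked at in mouse SMC cells without a test of the set. Of these 7 passed, where 2360 of all 10601 genes did. The activators Arntl (2.06 ± 0.30, limma adjusted p = 0.021) and Npas2 (2.18 ± 0.37, adjusted p = 0.022) and the repressor Nfil3 (3.67) were higher in the knockout libraries. Dbp (−2.19), Per3 (−1.85), Nr1d1 (−0.54, adjusted p = 0.038) and Nr1d2 (−0.70, adjusted p = 0.045) were lower. Usp2 (1.07, adjusted p = 0.052) and Cry2 (−0.10) did not pass. Per2 (−1.57), Ciart (−1.46), Tef (−0.94), Bhlhe41 (−0.86) and Hlf (−0.83) did not pass either, nor did Clock (0.42), Cry1 (0.35) or Per1 (−0.29). In cluster 1 (FMC) Nfil3 stood at 2.92 (adjusted p = 0.014), Npas2 at 1.40, Arntl at 0.85, Per1 at 0.07, Dbp at −0.79, Per3 at −1.31 and Bhlhe41 at −1.38. Of the 17, none that was measured passed in CMC cells, where Per1 stood at 1.13, Nfil3 at 1.06, Bhlhe41 at 0.66, Npas2 at 0.11, Arntl at −0.35, Dbp at −0.54 and Per3 at −1.04. Bhlhe40, outside the 17, passed there (1.71) but not in SMC cells (−0.28). The hour at which tissue was collected is not given in the sources used here.

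SMC cells of knockout replicate 1, the library with most CMC cells, carried Spp1, a secreted bone matrix protein, at 45.6 corrected UMIs per cell, 23.96% of the level in its CMC cells (190), and 96.23% of them had at least 1 UMI. The 9 other CMC genes looked at were lower there as a percent of their CMC level: Sox9 5.09, Hapln1 3.05, Comp 2.58, Cytl1 2.03, Acan 1.67, Alpl 1.62, Col2a1 1.56, Chad 1.07 and Ibsp 1.05.

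The SMC class held the same 4 clusters in every library, in other shares. Cluster 0 held 50.9%, 54.4% and 49.3% of SMC cells in knockout replicates 1, 2 and 3 and 36.5% and 37.3% in the wild-type libraries, and cluster 3 held 26.4%, 14.8% and 10.1% against 32.6% and 29.1%. Cluster 5 held 7.5%, 8.7% and 4.4% against 12.5% and 13.3%, and in cluster 4 the genotypes overlapped (15.1%, 22.1% and 36.1% against 18.4% and 20.3%). Knockout replicate 1 had only 53 SMC cells, with 27, 14, 8 and 4 in clusters 0, 3, 4 and 5, so its shares are uncertain.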
